A study of Mus musculus with 3 samples.

How the data were processed

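Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in germinal centre (GC) B cells sorted from the spleens of mice infected with Plasmodium berghei ANKA, a rodent malaria parasite. There were 3 libraries in 2 groups. The deficient group held 1 library from mice with floxed Tbx21, the gene of the transcription factor T-bet, and a CD23-driven Cre recombinase, which is active in B cells. The wild-type group held 2 libraries from mice with the Cre and no floxed allele. Both sorts took CD4-negative, CD19-positive, CD138-negative, GL7-positive cells with low CD38, and the wild-type sort also required CXCR3, so the gate and the genotype changed together. The labels' protocols give sorting at day 10 and 15 after infection without saying which library came from which day. Nothing in the labels says that the wild-type libraries came from separate animals. Both wild-type titles carry the same identification number, while other labels of replicate 2 carry another, so these libraries may share a source. The p-values therefore measure only the spread between these libraries, which may be technical.

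The authors deposited a table of raw read counts for 69889 regions common to the 3 libraries, with a gene symbol and gene ID for each region. They also deposited a log2 CPM (counts scaled to library size) file per library, per the file headers, with 68439 of those regions. The sorted log2 CPM values of the 3 files differed by a median of 0.017 and 0.016 from those of the first, and by at most 0.643 and 0.499. The normalisation behind them is not given in the sources used here. The filter behind the missing 1450 regions is not given in the sources used here. Per the submitters' processing notes, the build was GRCm38 (mm10), and Subread 1.6.0, featureCounts, HOMER 4.7 and limma were used, with no role or order stated. Peak calling, duplicate removal, the Tn5 offset and blacklisting are not given in the sources used here. Duplicates would make counts less independent than the intervals assume, and an unshifted insertion site matters little for regions with a median width of 168 bases. The total count was 3144912 in the deficient library, 3595839 in wild-type replicate 1 and 3200160 in replicate 2, with median counts per region of 24, 26 and 23. The floor of 3 counts lay at 0.957 CPM in the deficient library. Coordinates are printed as deposited. Whether they count from 0 or from 1 is not stated.

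Counts were tested with the edgeR 4.0.16 quasi-likelihood test on the counts as deposited, with TMM factors, the default expression filter and Benjamini-Hochberg adjustment at 0.05. The group was the only term, which left 1 residual degree of freedom. The spread therefore came from the wild-type libraries and was shared across regions, and the lone deficient library was assumed to vary like them. The prior degrees of freedom of the fit were infinite. A region's own gap between the wild-type libraries therefore carried no weight in its p-value or SE. Each SE of an edgeR log2 fold change was back-calculated, as the absolute fold change over the square root of the test's F statistic. CPM values use the TMM factors. A fold change against 0 counts is given as a bound at 3 counts in the deficient library. With 1 to 3 counts, the ratio of the pooled wild-type level to the deficient level is given with a 95% exact binomial counting interval. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. All differences are deficient minus wild-type.

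Gene lists were tested with camera in limma 3.58.1, at a preset correlation of 0.01 and on log2 CPM with a prior count of 2, and again with an estimated correlation and with fry. There were 18 lists, covering T-bet-linked genes, light zone, dark zone, the GC programme, naive and memory B cells, plasma cells, antigen receptor signalling, MHC class II and antigen presentation, interferon response, chemokine receptors and adhesion, class switching, AP-1 factors, T cell, NK cell, myeloid and erythroid markers, marginal zone and age-associated B cells, and housekeeping genes. The MHC class II and antigen presentation list also held MHC class I genes. A region belonged to the gene that the deposited table gave it. The RefSeq table of GRCm38.p6 matched the gene ID of 97.5% of regions and holds no strand, so transcription starts could not be told from gene ends. The planned promoter class was therefore replaced by regions within 1000 bases of either end of a protein-coding gene. Exon and intron positions were not used here.

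Lists, alternatives, the test and the rule for named regions were fixed before the data were examined. The rule took every tested region of Tbx21 and Cxcr3, and the 12 regions with the largest log2 fold change in each direction among those past the threshold at or above the median abundance. These were limited to 1 region per gene, a gene within 100 kb, and no predicted gene names. It also took, per list, up to 4 regions with the smallest p, 1 per gene. Alternatives were other scaling factors, loess offsets on abundance or width, other filters, DESeq2 1.42.0, limma-voom, robust moderation, other thresholds, chromosomes and immunoglobulin loci left out, thinned counts and each wild-type library left out. Motif tests needed a genome, which was not used here.

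The test was tried on simulated counts for 65185 regions with 200 regions changed in the deficient library. The changed regions were drawn from those at or above the median abundance. Every library varied by edgeR's own trended dispersion, so the trial could not test how the lone library varies or rank the tools fairly. Of 50 regions per fold, it recovered 100% of 4-fold rises, 38% of 2-fold rises, 68% of 4-fold falls and 2% of 2-fold falls, with 7 false calls. With none changed it made 0 calls at adjusted p under 0.05. On the same counts DESeq2 recovered 48 of the 200 and limma-voom 89. R 4.3.3 and Python 3.11.15 were used. The wild-type libraries differed by more than independent counts would, with a chi-square of 1.97 per region over 61698 regions with at least 20 counts. PCR duplicates can also raise this value, so it does not show separate animals. They were counted as 2 replicates because the labels list them as separate samples.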

Results

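Accessibility was compared in splenic GC B cells of P. berghei ANKA-infected mice, between 1 T-bet-deficient library and 2 wild-type CXCR3+ libraries. T-bet, encoded by Tbx21, is a transcription factor of the T-box family, and Cxcr3, a chemokine receptor gene, is a known T-bet target. Totals lay between 3144912 and 3595839 counts per library. Of 69889 regions, 65185 passed the expression filter and were tested. The share of counts within 1000 bases of the end of a protein-coding gene was 29.2% in the deficient library and 32.3% and 33.5% in the wild-type libraries.

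The Tbx21 and Cxcr3 regions were examined first, as the labels set the libraries apart by deletion of Tbx21 and by a CXCR3 gate. A region 3.1 kb outside Cxcr3 (chromosome X, 101737244 to 101737450, mm10) fell in the deficient library. It held 5 counts there against 39 and 41, or 1.595 CPM against 11.9 ± 1.51 CPM (SD, n = 2), with a log2 fold change of -2.87 ± 0.58 (SE) and an adjusted p of 0.000361 by edgeR. The region inside Cxcr3 (chromosome X, 101734063 to 101734217) held 17 counts against 28 and 23, with a log2 fold change of -0.48 ± 0.49 and an adjusted p of 0.714. The remaining tested region, 20.5 kb away, had a log2 fold change of -0.37 ± 0.49 and an adjusted p of 0.787. With counts summed over its 3 regions, Cxcr3 held 40 counts against 90 and 91 and was called lower by edgeR, with a smaller log2 fold change of -1.02 ± 0.29 and an adjusted p of 0.0314. At Tbx21, the region at the gene's upper end (chromosome 11, 97115271 to 97115421) held 4 counts against 17 and 9, with a log2 fold change of -1.56 ± 0.93 and an adjusted p of 0.449. Another, 8.1 kb outside the gene (97123435 to 97123585), held 26 counts against 15 and 15, with a log2 fold change of 0.89 ± 0.50 and an adjusted p of 0.419. The other Tbx21 regions, inside the gene, held too few counts to be tested, with 4 against 3 and 1, 8 against 5 and 8, and 4 against 7 and 5. No difference at Tbx21 passed the test at this depth, the in-gene regions did not all lie lower in the deficient library, and which part of the gene the floxed allele removes is not given in the sources used here. DESeq2 (adjusted p 1), limma-voom (0.210) and limma on the authors' log2 CPM (0.505) did not call the Cxcr3 region, with log2 fold changes of -2.90, -2.77 and -3.22.

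**Figure D1:**
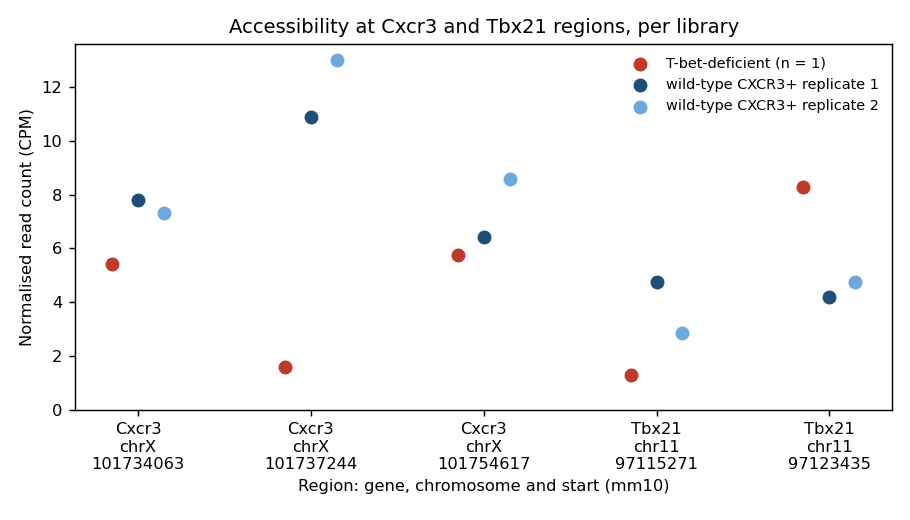
Normalised read count (CPM) per library at the tested regions of Cxcr3 and Tbx21, labelled by chromosome and start in mm10. Each point is 1 library. At the Cxcr3 region starting at 101737244, the deficient library lies at 1.595 CPM and the wild-type libraries at 10.9 and 13.0 CPM.

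Across the genome, 944 of 65185 regions (1.45%) passed the threshold, 533 higher and 411 lower in the deficient library. The higher regions had a median fold of 2.59 and the lower ones of 4.22, or 4.20 with the 37 regions at 0 counts in the deficient library set to their bound. These medians cover called regions only. In the simulation 2-fold falls were recovered in 2% of cases and 2-fold rises in 38%, so small falls passed less often. The medians thus do not compare the sizes of losses and gains. At least 2-fold against each wild-type library, at a prior count of 2 that pulls folds toward 0, were 343 of the higher and 325 of the lower regions. The count depended on the tool. DESeq2 called 4 regions, with 900 at an unadjusted p under 0.05, limma-voom called 441 (352 higher, 89 lower), and limma on the authors' log2 CPM called 0, with 6705 at an unadjusted p under 0.05.

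Among the largest losses, a region 21.9 kb outside Akirin2, which encodes a nuclear protein needed for NF-kB-dependent transcription (chromosome 4, 34528557 to 34528724), held 0 counts against 40 and 39 and was at least 12.3-fold lower (edgeR adjusted p = 2.10e-08). A region 91.5 kb from Klf4, the gene of a zinc-finger transcription factor (chromosome 4, 55623943 to 55624177), held 2 counts against 73 and 50, a ratio of 28.6 (95% interval 7.75 to 239). Regions near BC026585 and inside Npas3 held 3 counts each, with ratios of 21.4 (7.17 to 105) and 20.2 (6.75 to 99.0). Regions inside Dnajb12, which encodes a co-chaperone, and Acer1, an alkaline ceramidase gene (chromosome 17, 56963569 to 56963720), fell by 3.55 and 3.54 on the log2 scale, with SE of 0.51 and 0.47. Regions named for Speer7-ps1 and Speer4d, with ratios of 12.7 (4.20 to 62.9) and 11.9 (3.94 to 59.2), lie in a stretch of duplicated genes on chromosome 5 and share sequence with family members, so their counts are uncertain. At 4 of the 12 regions the size of the loss depended on wild-type replicate 1. Aim1l held 1 count against 390 and 20, and Gfi1b, which encodes a transcriptional repressor needed for erythroid and megakaryocyte development, 2 against 161 and 11. Camk2b held 6 against 208 and 8, and Il2ra, the interleukin-2 receptor alpha chain gene, 3 against 88 and 9. The ratios were 191 (34.0 to 7550) at Aim1l, 40.001 (10.9 to 333) at Gfi1b and 15.0 (4.996 to 74.2) at Il2ra. Camk2b fell by 3.99 ± 0.44 on the log2 scale, an SE that leaves out its gap between the wild-type libraries. Without replicate 1, the log2 differences of the 4 regions, as values with no test and a prior count of 2, were -2.87, -1.70, -0.32 and -1.13, and without replicate 2 they were -6.90, -5.20, -4.54 and -4.02. limma-voom called 1 of the 12, Acer1 (adjusted p 0.0384).

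Among the gains, a region inside Synpr, the synaptoporin gene (chromosome 14, 13361760 to 13361986), held 105 counts against 2 and 0, a ratio of 113 (95% interval 30.5 to 944), and was also called by DESeq2 (adjusted p 0.000857). A region inside Atf6, which encodes a sensor of the unfolded protein response (chromosome 1, 170729358 to 170729543), reached 39.2 CPM against 10.9 ± 0.79 CPM (SD, n = 2), with a log2 fold change of 1.85 ± 0.28 and an adjusted p of 4.01e-08 by edgeR. Regions inside Pdgfc, a growth factor gene, and Rasgrp3, which encodes a Ras activator in antigen receptor signalling (chromosome 17, 75521254 to 75521404), rose by 1.81 ± 0.33 and 1.76 ± 0.39 on the log2 scale. The regions of Tmtc4, Antxr2, Zbtb10, Fhit, Lpcat1, Arl6, Tnks and Tbata rose by 1.93, 1.93, 1.85, 1.77, 1.71, 1.71, 1.70 and 1.70. Another Tnks region (chromosome 8, 35123326 to 35123604) fell, with 33 counts against 118 and 87, a log2 fold change of -1.52 ± 0.31 and an adjusted p of 0.000418. limma-voom called all 12, with adjusted p between 1.68e-06 and 0.0127. The Synpr and Fhit regions lie in the first 20 Mb of chromosome 14, where calls were dense.

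**Figure D2:**
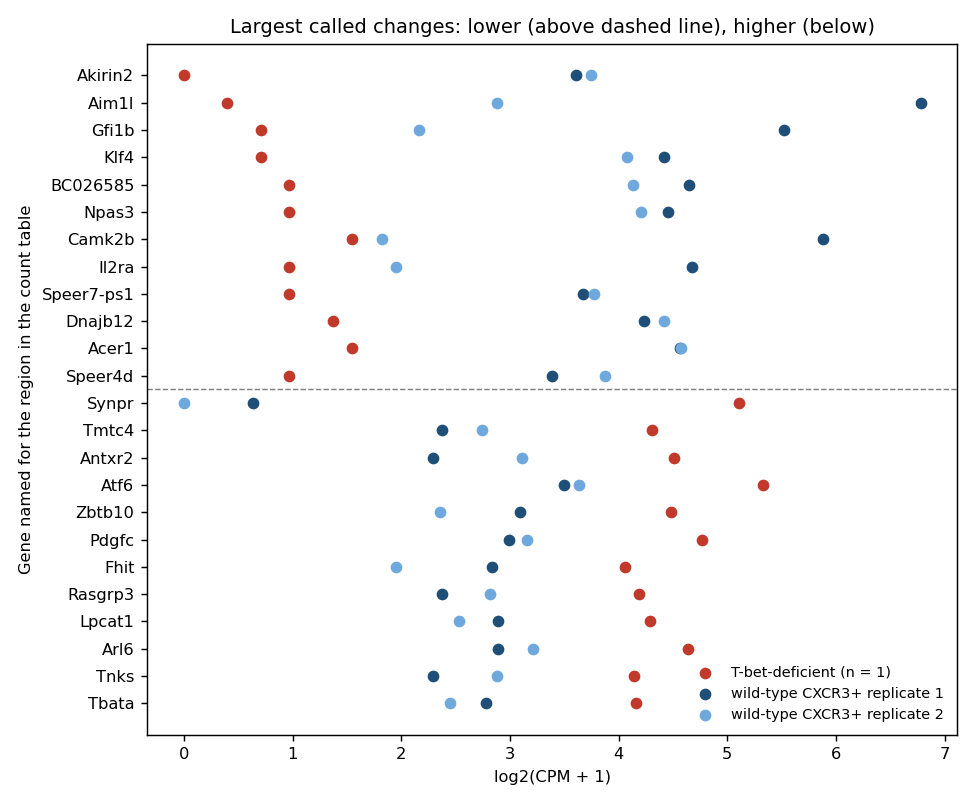
log2(CPM + 1) per library for the 12 regions with the largest called decrease (above the dashed line) and the 12 with the largest called increase (below it). Each point is 1 library. At Aim1l, Gfi1b, Camk2b and Il2ra, wild-type replicate 2 lies far below replicate 1.

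Called regions were unevenly placed. In the first 20 Mb of chromosome 14 and from 14 to 16 Mb of chromosome 5, stretches chosen after their values were seen, 107 of 461 tested regions were called (23.2%), against 837 of 64724 elsewhere (1.29%). From 14 to 16 Mb of chromosome 5, which holds Speer genes, all 30 calls were lower, and 95% of the 80 tested regions lay below 0 (median log2 fold change -1.47). From 3 to 8 Mb of chromosome 14, 44 of 48 calls were lower, with a median of -2.57 over 171 tested regions. From 8 to 20 Mb, 17 of 29 calls were higher and the median over 210 regions was 0.021. Without these stretches, 739 regions were called, 444 higher and 295 lower.

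**Figure D3:**
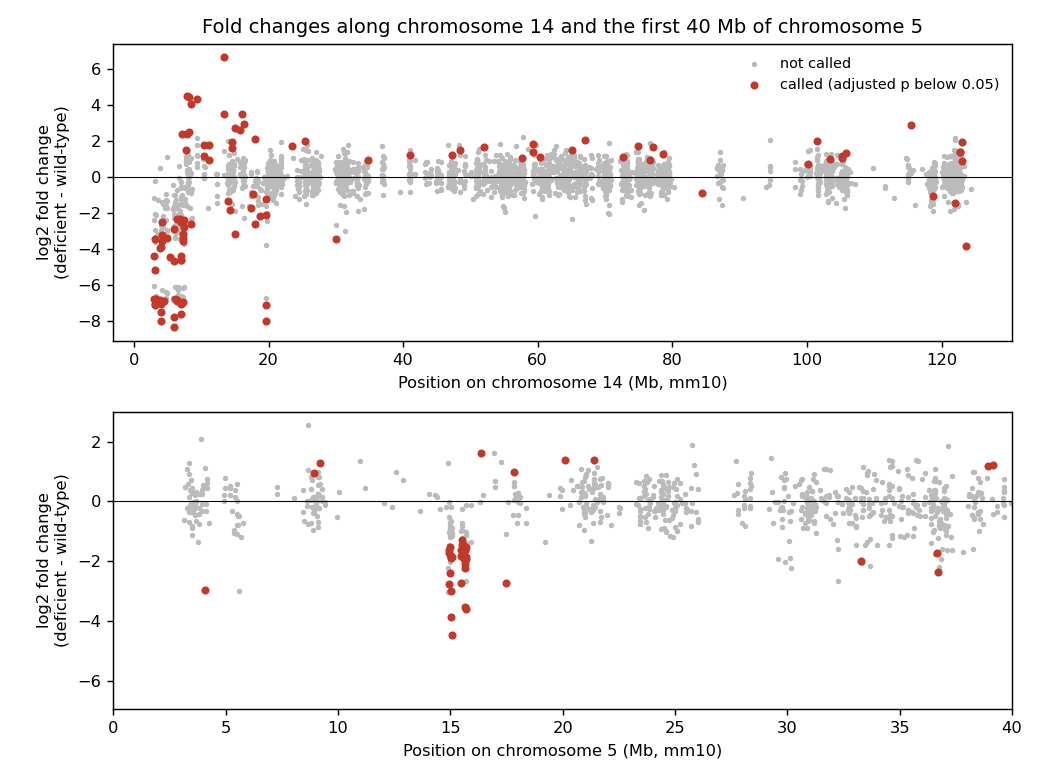
log2 fold change (deficient minus wild-type) of each tested region along chromosome 14 and the first 40 Mb of chromosome 5, in Mb of mm10. Red points passed an adjusted p of 0.05 by edgeR. Calls crowd in the first 20 Mb of chromosome 14 and near 15 Mb of chromosome 5.

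Over regions, camera called 0 of 18 lists, with 4 at an unadjusted p under 0.05 and a lowest adjusted p of 0.212; with an estimated correlation or with fry none was called. With counts summed per gene, camera called light zone genes (adjusted p 0.0480) and T cell markers (0.0246) upward. It also called MHC class II and antigen presentation genes upward (0.0480). With an estimated correlation on the same sums, an alternative chosen after seeing the data, none was called (0.775 for each of these lists). Single regions did pass the threshold within most lists. The share called over all tested regions was 1.45%, so a few calls in a list do not by themselves set it apart.

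Among T-bet-linked genes, 1 of 83 regions rose and 3 fell, or 1 and 4 adjusted over the list alone. Beside Cxcr3, a region 104 kb from Ifng, the interferon-gamma gene, fell by 2.08 ± 0.53 on the log2 scale (adjusted p 0.0146), and one 31.7 kb from Fasl, a death ligand gene, rose by 1.13 ± 0.32 (0.0346). A region inside Zeb2 had a log2 fold change of -1.40 ± 0.45 and an adjusted p of 0.0841. The list's median was 0.20 and its mean -0.012, which differ in sign. In the marginal zone and age-associated list, 1 of 181 regions rose and 0 fell (0 and 0 adjusted over the list alone), inside Cd36 (0.99 ± 0.29).

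In the light zone list, named for the GC compartment of T cell help, 2 of 189 regions rose and 1 fell (2 and 1 adjusted over the list alone). A region inside Cd83, an activation marker, rose by 1.22 ± 0.31 (adjusted p 0.0143) and one shared by Ubac2 and Gpr183, a migration receptor gene, fell by 1.45 ± 0.38 (0.0208). In the dark zone list, the compartment of proliferation, 1 of 219 rose and 0 fell (1 and 0 adjusted over the list alone), near Cenpe (1.06 ± 0.26), a kinetochore motor gene. Aicda, the gene of the mutating deaminase, had a region at 0.74 ± 0.22 with an adjusted p of 0.0582. Of the GC programme, 2 of 246 rose and 0 fell (0 and 0 adjusted over the list alone), inside Ebf1 (1.81 ± 0.52), a B lineage factor, and next to Rgs13 (0.75 ± 0.22). In the class switching list 1 of 139 rose and 0 fell (0 and 0 adjusted over the list alone), 25.1 kb outside Exo1 (0.95 ± 0.28).

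Among naive and memory genes, 2 of 278 regions rose and 3 fell, as when adjusted over the list alone. Regions inside Ski (0.89 ± 0.20) and Bcl2 (1.10 ± 0.29), a survival gene, rose. A region 209 kb from Tle3 held 1 count against 35 and 9, a ratio of 20.5 (3.49 to 826), and limma-voom did not call it (adjusted p 0.494). Its log2 difference was -1.87 without wild-type replicate 1 and -3.50 without replicate 2. These are values with no test and a prior count of 2, which pulls them toward 0, so they are not on the scale of the ratio. Of plasma cell genes, 0 of 151 rose and 3 fell, also adjusted over the list alone, among them regions near Ly6c2 (-1.63 ± 0.27) and Il10 (-1.91 ± 0.55), the interleukin-10 gene. In the antigen receptor list, 2 of 282 rose and 2 fell, also adjusted over the list alone: regions 80.4 kb outside Card11 (1.19 ± 0.33) and inside Inpp5d (1.37 ± 0.39) rose, and regions 2.03 kb outside Cd72 (-2.32 ± 0.65) and inside Plcg2 (-2.17 ± 0.61) fell. Of chemokine receptor and adhesion genes, 1 of 224 rose and 4 fell (2 and 5 adjusted over the list alone), among them a region 39.9 kb outside Itgb1 (-2.50 ± 0.49) that fell and a region inside Itga4 (0.94 ± 0.26) that rose, both integrin genes. In the AP-1 list 0 of 102 rose and 1 fell, also adjusted over the list alone, inside Jund (-2.25 ± 0.60). The MHC class II and antigen presentation list and the interferon response list had 0 calls by edgeR among 68 and 120 regions, also adjusted over the list alone. Each had 13 regions at an unadjusted p under 0.05 and 0 calls by limma-voom or DESeq2. With counts summed per gene, edgeR called H2-Ob (0.76 ± 0.19), Ctss (0.86 ± 0.24), H2-Eb1 (0.52 ± 0.15) and H2-Aa (0.52 ± 0.15) higher, with adjusted p of 0.00685, 0.0268, 0.0345 and 0.0354. In the same fit, edgeR called the T cell markers Cd4 (1.40 ± 0.43) and Ctla4 (0.49 ± 0.14) higher, and camera called that list only at the preset correlation (adjusted p 0.0246, against 0.775 with an estimated one).

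Markers of other cell types were tested as a check of the gate. T cell markers had 0 calls by edgeR among 87 regions (camera p 0.0197 upward, adjusted 0.212), NK cell markers 0 among 32, and housekeeping genes 0 among 66, also adjusted over each list alone. Of these, 13, 1 and 6 regions had an unadjusted p under 0.05, and limma-voom and DESeq2 called 0. With counts summed per gene, Cd4 (from 1 region) and Ctla4 had adjusted p of 0.0452 and 0.0238. Of myeloid markers, 1 of 74 rose, near Siglech (1.20 ± 0.35), and 2 fell, among them one inside Mafb (-1.08 ± 0.29), with 1 and 3 adjusted over the list alone. Of erythroid markers, 0 of 19 rose and 1 fell, also adjusted over the list alone, a region 130 kb from Gypa (-1.55 ± 0.27), with a list median of -0.37 (camera p 0.0251 downward, adjusted 0.212). With counts summed per gene, edgeR called Gypa lower (-1.20 ± 0.21, adjusted p 9.26e-06), and camera did not call the list (adjusted p 0.0881). In the same fit edgeR also called Hbb-b1 lower (-0.74 ± 0.18, adjusted p 0.00452), a gene that the fixed list does not name. limma-voom called 9 of the 26 list regions that edgeR called among those named by the rule. Of the 12 lower ones it called only those of Gypa and Ly6c2 (limma-voom adjusted p 0.000569 and 0.000244). It did not call those of Cxcr3, Ifng, Il10, Cd72, Plcg2, Jund, Itgb1, Gpr183, Mafb and Tle3 (0.0632 to 0.494). Of the 14 higher ones it did not call those of Card11, Inpp5d, Exo1, Ebf1, Bcl2a1d, Cd36 and Siglech.

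**Figure D4:**
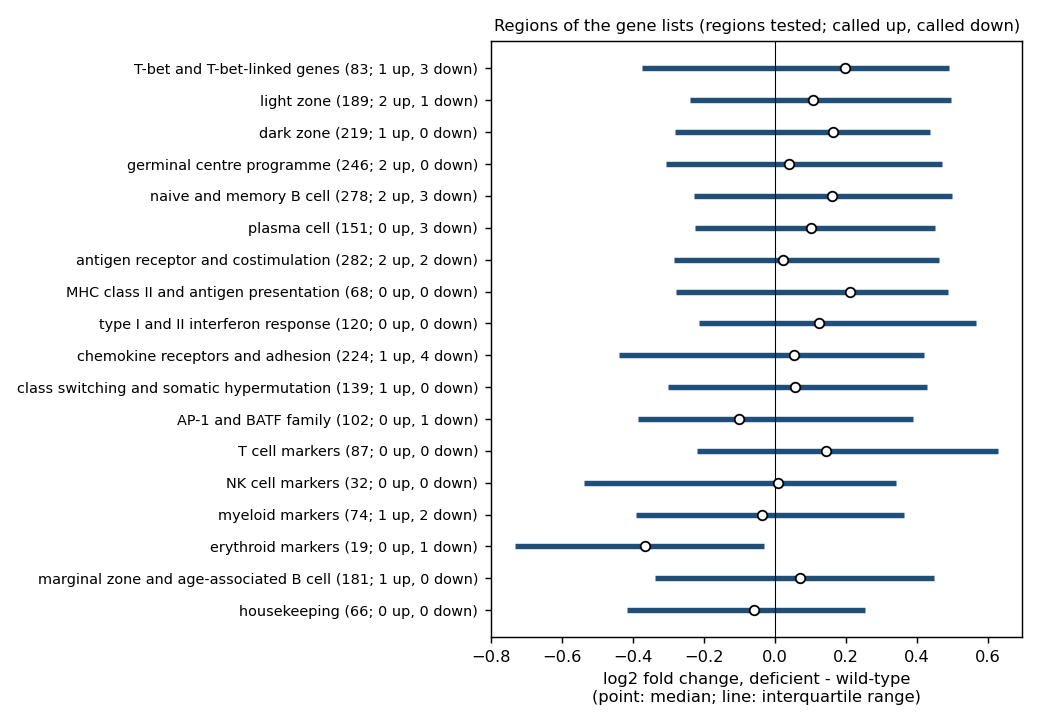
Median (point) and interquartile range (line) of the log2 fold change, deficient minus wild-type, over the tested regions of each list, with regions tested and called in brackets. The medians lie between -0.37 (erythroid markers) and 0.21 (MHC class II and antigen presentation).

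Regions near gene ends and regions elsewhere differed. Near ends, 42 of 17844 regions were called higher (0.235%) against 491 of 47341 elsewhere (1.04%), an odds ratio of 0.23 (95% interval 0.16 to 0.31, two-sided Fisher's exact p = 8.42e-30). For lower calls the shares were 0.532% and 0.667%, with an odds ratio of 0.80 (0.63 to 1.01, Fisher's exact p = 0.0522). The median log2 fold change was -0.20 near ends and 0.077 elsewhere. Regions are not independent replicates, and the wild-type libraries differed in the same measure by -0.047 near ends and 0.019 elsewhere.

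The deficient library lay farther from each wild-type library than these lay from each other. The SD of the log2 CPM difference over regions was 0.65 against replicate 1, 0.65 against replicate 2 and 0.52 between the wild-type libraries. Regions over 2-fold apart made up 11.1%, 11.4% and 5.86%. The wild-type libraries share a genotype and a gate and may share a source, so this difference cannot be assigned to T-bet.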

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

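The alternatives that used the authors' log2 CPM, left out regions over 1000 CPM, left out regions with wild-type libraries over 2-fold apart, left out the clustered stretches, or estimated the correlation of lists on counts summed per gene were chosen after seeing the data. The count of 944 regions lay between 739 and 1126 under 14 alternatives of scaling, filter, moderation, depth, fold minimum and regions left out. It was 4 with DESeq2, 441 with limma-voom, 1849 at an adjusted p under 0.10, 0 with the authors' log2 CPM, and 1771 without regions whose wild-type libraries were over 2-fold apart, a selection that shrinks the spread by construction. DESeq2 used a median dispersion of 0.181, and edgeR estimated a common one of 0.0173. The former is a median over regions and the latter a single value for all regions, so they are unlike measures. On the counts simulated from edgeR's own dispersion with 200 regions changed, DESeq2 gave 0.160 and edgeR 0.0172. A gap of this kind between the tools thus also arose where the dispersion was edgeR's. DESeq2 also left 25746 regions without an adjusted p. Which of these lowers its count was not tested, and the cause of the other differences was not tested either. The share of higher calls was 56.5% with TMM, 49.8% with upper-quartile factors and 79.8% with limma-voom. Without wild-type replicate 1, 753 of the 944 regions kept their direction at 2-fold or more, and without replicate 2, 786 did. These are values with no test on regions selected from the same libraries. The main fit had 823 at 2-fold or more. The values without a replicate use a prior count of 2, which pulls them toward 0, so part of the drop may come from that.

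The Cxcr3 region had log2 fold changes of -2.90 with DESeq2, -2.77 with limma-voom and -3.22 with the authors' log2 CPM, no longer past the threshold; the cause was not tested. It kept its call in the other alternatives that tested it. With counts summed per gene, camera called light zone genes (adjusted p 0.0480) and T cell markers (0.0246) upward. It also called MHC class II and antigen presentation genes upward (0.0480). With an estimated correlation none of the 3 was called, over regions (0.830 each) or on these sums (0.775 each). No list was called over regions near gene ends or away from them. Near ends, camera gave unadjusted p of 0.932 (upward) for light zone genes and 0.772 (downward) for T cell markers. For MHC class II and antigen presentation genes it gave 0.517 (upward). Away from ends, these lists had 0.0157, 0.00785 and 0.0487, all upward, in that order. Both gene-end odds ratios kept their side of the threshold under all 3 alternatives. Of 49 called regions named outside Tbx21 and Cxcr3, DESeq2 ended the call of 46, limma-voom of 27 and the authors' log2 CPM of 49, and 6 other alternatives of 1 to 5.

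No paired analysis was possible because the groups share only replicate number 1. Motif alternatives and the GC content correction were not run without a genome, and width took the place of GC content. At the depth of these libraries, simulated 2-fold falls were recovered in 2% of cases and 2-fold rises in 38%, for regions at or above the median abundance only.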

Other observations

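All tests of explanations here were chosen after the results were seen, as were the regions named outside the fixed rule. At the immunoglobulin heavy chain constant genes (chromosome 12), where class switching deletes DNA, edgeR called 0 of 17 regions over all regions, with 3 at an unadjusted p under 0.05, and 2 when adjusted over these alone; limma-voom called 1 and DESeq2 0. The Ighg2c region held 4 counts against 10 and 14, with a log2 fold change of -1.46 ± 0.96 and an adjusted p of 0.505. Those of Ighg2b held 74 against 38 and 46 (0.91 ± 0.30, adjusted p 0.0929) and of Ighg1 60 against 36 and 37 (0.82 ± 0.33, 0.198). The stronger Ighg3 region held 39 against 9 and 20 (1.51 ± 0.45, 0.0518). With counts summed over its 2 regions, Ighg3 held 56 against 16 and 31 and was called higher (1.40 ± 0.39, adjusted p 0.0211).

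With counts summed per gene, 264 genes were called higher and 170 lower among 18013. Regions inside Cd244, a SLAM family receptor gene (-1.64 ± 0.36), and Tc2n (-1.41 ± 0.28) fell, and regions inside Lama1, a laminin gene (1.35 ± 0.20), and Stap1, an adaptor gene (1.16 ± 0.24), rose. All 4 were also called by limma-voom (adjusted p 0.0345, 0.00276, 3.55e-11 and 0.00143).

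Calls clustered on chromosomes 5 and 14. Of 958 windows of 2 Mb, 11 had at least 10% of regions called, and 7 of these lay in the stretches, as did 3 of the 4 DESeq2 calls (Synpr, Oxsm and Gm21149, the other being Strn). With thinned counts the share called was still 21.0 times that elsewhere. This cannot decide on lower depth. The stretches were chosen for their calls in the same counts, and the total of the deficient library was already close to that of wild-type replicate 2. In 8 to 20 Mb of chromosome 14, regions of genes outside the Gm, Rik and Speer names were called 9.61 times as often as elsewhere. This cannot decide on shared reads of gene families. The stretch was chosen for its calls, and names do not show where reads map uniquely. A DNA difference between the mice, in copy or strain haplotype, may lie behind the family stretches, where the median over all tested regions was -2.04, and behind 8 to 20 Mb, where even uncalled regions scattered 1.35 times as widely as elsewhere and the wild-type libraries 1.05 times. Shared reads in any of these stretches stay open, as does an effect of T-bet itself, of the CXCR3 gate or of the sorting day. The deficient group is a single library that differs from the wild type in genotype and gate together, and its sorting day is not known.

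Of 22 lower calls with wild-type libraries over 4-fold apart, 20 were higher in replicate 1, at 6 genes that include Gfi1b, Il2ra and Aim1l. A signal over short blocks of DNA in that library may account for these, with 19 of the 20 regions within 5 kb of another, and 26 regions of the same genes farther away differed by a median of -0.018 between the wild-type libraries. The blocks may be a feature of replicate 1 alone, or a group effect (T-bet, CXCR3 gate or day) shared in part by replicate 2. Which it is stays open, since the 20 were selected for the gap between the replicates. The 5 tested regions within 5 kb that were not selected had a median of 1.13 (replicate 1 minus replicate 2, interquartile range 0.25 to 1.64). Replicate 2 minus the deficient library had a median of 0.16 (0 to 0.58) in these 5. In the 20, which were selected as lower calls, that median was 1.08 (0.32 to 1.61). The 5 regions are too few to decide. limma-voom called 1 of the 22.

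Regions near gene ends lay below the others by 0.28 on the log2 scale. Lower depth and a trend with abundance are argued against as the whole cause, since the gap was 0.276 with thinned counts and 0.258 with loess offsets. A lower signal over background in the deficient library could not be told apart from an effect of T-bet, the CXCR3 gate or sorting day. The 34 near-end regions of housekeeping genes had a median of -0.078 and an interquartile range of -0.36 to 0.037. Of the 34, 67.6% lay below 0, near the 69.0% of all near-end regions and above the 44.7% of other regions.

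With each library in turn as the lone one, the deficient library gave 944 regions and the highest of the others 13; 1 of the 3 choices gave as many as 944, and 3 choices are too few for a share under 0.05.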
